A study of Mus musculus with 6 samples.

How the data were processed

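Lineage-depleted bone marrow cells with high to intermediate KIT were taken from 3 mice of each of 3 genotypes (WT, DC and DE, variants of an enhancer at -165 kb from Zeb2). They were marked with 3 TotalSeq B hashtag antibodies and pooled into 1 library per genotype. Libraries were made with the 10x Genomics 3' v3 kit and sequenced on a NovaSeq 6000 with 150-bp paired reads, all per the labels' protocols. The deposited matrices hold counts of UMIs per cell barcode for 32285 genes and 3 hashtags, not normalized, per the file headers. The headers name Cell Ranger 7.2.0, while the submitters' notes name 8.0.0 and the build mm10. The gene annotation, the cell calling settings and whether counting used strand or introns are not given in the sources used here. Coordinates of Zeb2 are those of GRCm38.p6 in a gene table, and no genome sequence was used here. Gene symbols were those that the deposited files pair with their identifiers.

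A barcode was kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, which left 14545 WT, 12668 DC and 14744 DE barcodes. Mice were told apart by HTODemux in Seurat 5.3.0 (quantile 0.99). This gave 12322, 11390 and 12995 barcodes with 1 hashtag, 1640, 921 and 1323 with several hashtags (11.3%, 7.27% and 8.97% of barcodes kept) and 583, 357 and 426 with none. Barcodes with several hashtags were removed as doublets between mice. The number of doublets within a mouse was computed from them (821, 461 and 662), and as many barcodes with 1 hashtag, those with the largest share of known doublets among their 50 nearest neighbours, were removed. This left 11501, 10929 and 12333 cells.

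Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen over the libraries (scanpy 1.11.5, Seurat dispersion), leaving out Zeb2, sex-linked, cell cycle, ribosomal and mitochondrial genes. The cells were clustered on 40 principal components by the Leiden method (igraph 0.11.9, 20 neighbours, resolution 2). The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and matplotlib 3.10.9 for figures. A cluster was named after the list of cell type markers with the highest score if at least 3 of its markers were over 2-fold higher than in the other cells and no other list had more genes among its top 10 genes. Mixed clusters were clustered once more on their own (resolution 1), and clusters that met no rule stayed unnamed. The dendritic classes were clustered again in the same way.

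Cells are not replicates, so UMI counts were summed per mouse and class, and the 3 mice of each genotype were the replicates (a mouse entered a class with at least 20 cells). Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood fit over all 9 mice) for DC minus WT, DE minus WT and DE minus DC, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Shares of classes and dendritic subclusters were tested with the same method on cell numbers, with the number of kept cells of the mouse as offset and the adjustment over the classes or subclusters of a contrast. CPM are UMIs of a gene per 1000000 UMIs of a mouse's class after TMM scaling, computed here from the deposited counts. Summed levels of the Neutrophil list are CPM without TMM scaling. A difference in the Zeb2 effect between a class and the stem and multipotent-like class was tested as an interaction in 1 fit. Where a group had 0 counts, 3 counts over the group were the floor.

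The cell type markers, the gene lists, the rule for named genes and the first group of alternatives were fixed before the data were examined. The named genes were Zeb2, then the genes past the test whose mice did not overlap with the largest changes (10 each way in the dendritic and monocyte-like classes, 4 each way in others), then members of 16 gene lists past the test. Sex-linked genes were left out of the ranking. The lists were E proteins and inhibitors, Dendritic transcription factors, cDC1, cDC2, pDC, Monocyte, Neutrophil, Early lymphoid, MHC class II, Interferon-stimulated, Cell cycle S, Cell cycle G2/M, Dissociation and stress, Zeb2 neighbours on the chromosome, Erythroid and Mitochondrially encoded. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and, as an alternative, an estimated correlation, adjusted over the lists of a class and contrast. Genes of near-identical families, such as histone and immunoglobulin genes, are uncertain.

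The tests were run on simulated data first. For DC minus WT, 200 genes were changed in counts drawn from the real means, and those past the filter on low counts (63 to 67 per class and size) were scored. Of these 53.7%, 82.1% and 96.9% of changes of 0.5, 1 and 2 on the log2 scale were recovered in the stem and multipotent-like class (12334 genes). The values were 58.2%, 77.6% and 97.0% in neutrophil-like (14211 genes), 62.1%, 84.8% and 93.9% in monocyte-like (12527 genes) and 33.3%, 60.6% and 90.9% in cDC-like cells (10208 genes). Of the calls 7.78%, 4.91%, 3.64% and 7.63% were false. The share test recovered 96% of 3-fold falls in 100 simulations, with 0.615% false calls. Falls forced by another class's rise were not simulated.

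The first group of alternatives was a hashtag ratio rule (10 counts, 3-fold), a stricter cell filter (1000 genes, 2500 UMIs, 5% mitochondrial), removal only of cells with several hashtags, classes from the WT library alone and Leiden resolution 1. It also held TMM over classes, the hashtag number as a block, leaving out each mouse, RLE scaling, DESeq2 1.42.0, no filter on low counts, only the 6 mice compared, at least 50 cells per mouse, cells thinned to 5000 UMIs, and the estimated correlation. After the data were seen, only clusters to which each genotype gave at least 10% of the cells, and the block and left-out mice for gene lists, were added.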

Results

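Bone marrow progenitors of mice of 3 genotypes, labelled WT, DC and DE, were profiled by droplet-based single-cell RNA sequencing, which counts RNA molecules by unique molecular identifiers (UMIs). The genotypes are variants of an enhancer named by its position at -165 kb from Zeb2, a gene that encodes a zinc-finger transcriptional repressor active in blood cell development. What DC and DE change in the enhancer is not given in the sources used here. Cells carrying CD19, B220, CD3e, CD8b, CD11b, TER-119 or Ly-6G had been depleted, and cells with high to intermediate KIT, the receptor for stem cell factor, had been sorted, so every share of cells is a share of this sorted population. Each genotype had 3 mice, marked by antibody hashtags and pooled into 1 library. The mice are the replicates, and n = 3 per genotype holds for every mean, SD and test. With 1 library per genotype, differences between genotypes and between libraries cannot be told apart.

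The libraries held 16871 (WT), 14085 (DC) and 16171 (DE) barcodes, with 346406583, 296061712 and 304849770 gene UMIs. After filtering, assignment to mice and removal of doublets, 11501 WT, 10929 DC and 12333 DE cells remained. A mouse gave 3602 to 4217 cells, 76392578 to 89367099 UMIs and a median of 15887.5 to 20904.5 UMIs per cell. In each genotype the mouse with hashtag 3 had high Xist and low Ddx3y counts and the others the reverse, so the genotypes did not differ in this. Clusters of cells were named by fixed markers only, which gave 13 classes, written as "monocyte-like" and so on.

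The first question was whether the enhancer variants changed the level of Zeb2 (ENSMUSG00000026872; chromosome 2, 44983512 to 45117442 in GRCm38.p6). Zeb2 was lower in both variants. Over all cells it stood at 575 ± 30.9 (SD) in WT, 134 ± 6.63 in DC and 205 ± 11.2 in DE, in UMIs per 1000000 UMIs after TMM scaling (CPM). The log2 fold change was -2.10 ± 0.06 (SE, adjusted p = 1.22e-08) for DC and -1.48 ± 0.06 (adjusted p = 1.38e-07) for DE against WT. DE lay above DC by 0.62 ± 0.06 (adjusted p = 0.000682). These values rest on 148402, 30934 and 47405 Zeb2 UMIs. Values over all cells also follow shifts between classes with high and low Zeb2. The enhancer lies outside the transcript, so the UMIs measure Zeb2 RNA and do not show the alteration itself.

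The fall in Zeb2 differed between some classes. In the neutrophil-like class Zeb2 went from 193 ± 11.1 CPM in WT to 7.23 ± 0.804 in DC and 24.7 ± 2.02 in DE (log2 fold changes -4.76 ± 0.08 and -2.98 ± 0.08; adjusted p = 1.29e-12 and 2.74e-11). In the monocyte-like class it went from 1247 ± 61.4 to 199.8 ± 40.5 in DC and 705 ± 39.2 in DE (-2.62 ± 0.14 and -0.81 ± 0.13; adjusted p = 5.05e-06 and 0.00333). That class was filled by different clusters in the genotypes. In cluster 31 (328 WT, 72 DC and 98 DE cells), the only one shared by the genotypes and chosen after seeing the data, the values were -2.03 and -1.23. In the stem and multipotent-like class it fell by 1.74 ± 0.15 in DC and by 1.52 ± 0.14 in DE on the log2 scale (adjusted p = 9.69e-05 and 0.000227). In the basophil and mast-like class it fell by 1.75 ± 0.19 and 1.20 ± 0.18 (adjusted p = 0.00124 and 0.00803). Neither variant passed the test in the megakaryocyte-like class (1297 ± 137 CPM in WT, 1265 ± 241 in DC, 1104 ± 95.8 in DE) or in the erythroid-like class (365 ± 18.4, 347 ± 14.5 and 335 ± 2.65 CPM). In the lymphoid progenitor-like class Zeb2 fell in DE from 447 ± 86.7 to 149 ± 24.2 CPM (-1.62 ± 0.14, adjusted p = 5.06e-08) and in DC to 294 ± 26.5 (-0.62 ± 0.14, adjusted p = 0.0110). The DC call was lost with classes from the WT library alone (-0.42), after thinning (-0.46) and without WT mouse 3 (-0.46) or DC mouse 3 (-0.56). DE lay below DC there (-0.999 ± 0.14, adjusted p = 0.000504; -2.74 with classes from the WT library alone and -1.60 after thinning). In the conventional dendritic (cDC)-like class the WT mice themselves ranged widely (116 ± 70.0 CPM). The levels of 32.6 ± 18.1 in DC and 89.7 ± 11.9 in DE did not pass (adjusted p = 0.204 and 0.801). Without WT mouse 2 the DE to WT value there changed sign, from -0.37 to 0.11. With classes taken from the WT library alone the lymphoid value for DE was -3.15.

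**Figure D1:**
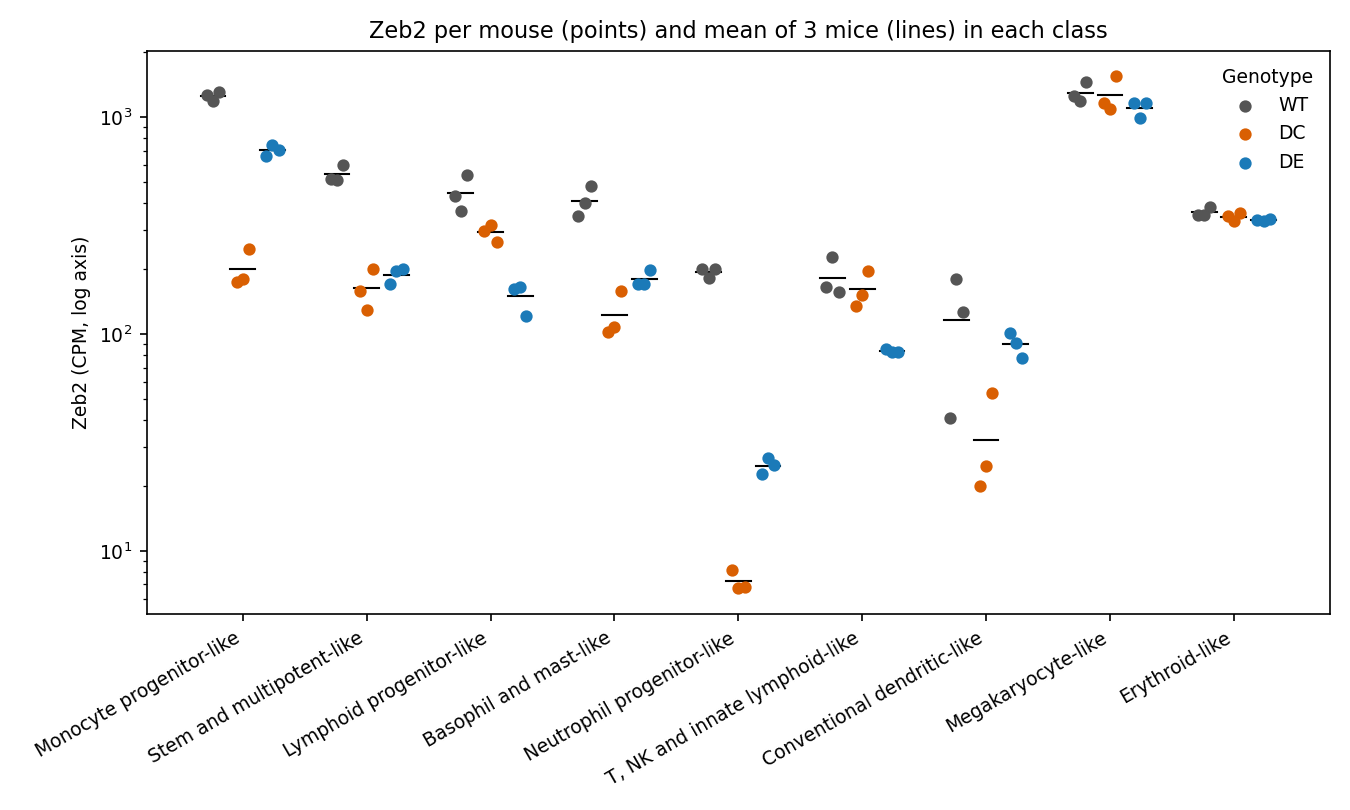
Zeb2 level (CPM, log axis) in each class of cells for the WT, DC and DE mice; points are single mice and lines are means of 3 mice. In the neutrophil-like class the means were 193 (WT), 7.23 (DC) and 24.7 (DE) CPM, while in the megakaryocyte-like class they were 1297, 1265 and 1104.

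Shares of cells with a Zeb2 UMI were compared after thinning every cell to 5000 UMIs, which left out 359 WT, 282 DC and 495 DE cells. Over all cells the share was 64.4% in WT, 20.01% in DC and 25.0% in DE. It was 36.1%, 2.34% and 6.46% in the neutrophil-like class and 97.9%, 53.3% and 89.5% in the monocyte-like class. Plasma cell-like cells, taken as cells that should lack Zeb2, had a UMI in 3 of 98 WT cells (3.06%, exact 95% Clopper-Pearson interval 0.636 to 8.69%, median 18882.5 UMIs per cell) and in 3 of 52 DC cells (5.77%, 1.21 to 15.9%, median 25029). These intervals cover counting error only. The DC share in the neutrophil-like class (1.99 to 2.73%, median 19011.5 UMIs) was not distinguishable from this background, and the WT share (median 18600 UMIs) lay above it. The DE share (5.91 to 7.05%, median 15741 UMIs) lay above that of DC. DE had no plasma cell-like cells, so its own background was not measured. How much of the 7.23 and 24.7 CPM in that class was the cells' own RNA was not measured, which limits the fold changes there. Without thinning the shares over all cells were 77.8%, 31.5% and 36.2%.

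The next comparison asked how the variants changed the makeup of the progenitors. cDC-like and neutrophil-like cells took a larger part and monocyte-like cells a smaller part of both variants. The cDC-like cells, named by markers such as Batf3, Zbtb46 and MHC class II genes, rose from 2.16 ± 0.1002% of WT cells to 4.68 ± 0.663% in DC (2.17-fold, log2 fold change 1.12 ± 0.17, adjusted p = 0.000313). In DE they were at 5.62 ± 0.387% (2.60-fold, 1.38 ± 0.16, adjusted p = 4.56e-05). Monocyte-like cells fell from 19.6 ± 1.09% to 6.10 ± 0.403% in DC (3.22-fold, -1.69 ± 0.14, adjusted p = 3.61e-06). They fell to 8.56 ± 0.593% in DE (2.29-fold, -1.20 ± 0.14, adjusted p = 4.56e-05). This share pools clusters that moved in opposite directions. Clusters 19, 27 and 33 held 7.64%, 4.88% and 3.51% of WT cells, 0.0182%, 0.0916% and 0.0276% of DC cells and 0.619%, 0.237% and 0.347% of DE cells. Clusters 21 and 29, with 1 and 0 monocyte markers among their top 10 genes, held 0.0597% and 0.0168% of WT, 3.09% and 2.15% of DC and 3.73% and 2.45% of DE cells. Neutrophil-like cells rose from 38.1 ± 4.06% to 62.2 ± 4.93% in DC and 61.4 ± 1.70% in DE (1.63-fold and 1.61-fold, adjusted p = 0.00234 and 0.00107). The depletion of CD11b and Ly-6G cells and the KIT gate act on these classes and can set their shares.

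Lymphoid lineage cells moved in different directions. Cells with markers of T, NK and innate lymphoid cells rose from 1.14 ± 0.168% in WT to 3.78 ± 0.951% in DE (3.29-fold, log2 fold change 1.72 ± 0.25, adjusted p = 0.000145). At 1.503 ± 0.388% in DC they did not pass (adjusted p = 0.207). Plasmacytoid dendritic (pDC)-like, B lineage-like and plasma cell-like cells were 0.554 ± 0.141%, 0.681 ± 0.198% and 0.858 ± 0.441% of WT cells. In DE they were 0 of 12333 cells, a count that allows a share of up to 0.0243% for each. Against this limit, 3 cells over the DE group, WT was at least 22.9-fold higher for pDC-like, at least 27.9-fold for B lineage-like and at least 35.0-fold for plasma cell-like cells (adjusted p = 0.000854, 8.93e-05 and 0.000145). In DC, B lineage-like cells fell 3.86-fold to 0.173 ± 0.0826% (adjusted p = 0.00492) and pDC-like cells 6.53-fold to 0.0818 ± 0.119% (adjusted p = 0.00996). Plasma cell-like cells at 0.485 ± 0.124% did not pass (adjusted p = 0.112). B220, CD19 and CD3e were depletion targets, so these shares are of cells that escaped the depletion. The pDC-like log2 fold change in DC was -2.71. It was -5.04 without DC mouse 3, -1.55 with classes from the WT library alone and -1.74 at the lower cluster resolution, where the call ended (adjusted p = 0.0535). In DE it was -1.63 with classes from the WT library alone. The plasma cell-like value was -3.54 where only cells with several hashtags were removed as doublets. The bounds against 0 DE cells therefore hold only under the main rules for classes and doublets.

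Megakaryocyte-like cells fell 2.03-fold in DC and 2.79-fold in DE, from 5.04 ± 0.670% to 2.49 ± 0.958% and 1.81 ± 0.322% (adjusted p = 0.00895 and 0.000799). Erythroid-like cells fell from 10.6 ± 3.30% to 5.41 ± 1.02% in DE (log2 fold change -0.97 ± 0.23, adjusted p = 0.00268). Basophil and mast-like cells fell in DE from 4.20 ± 0.733% to 2.59 ± 0.455% (-0.69 ± 0.21, adjusted p = 0.00931). Unnamed cells fell from 5.33 ± 0.400% to 3.38 ± 0.529% in DC and 3.14 ± 0.373% in DE (adjusted p = 0.00895 and 0.00182). Of the 14 groups, 13 classes and the unnamed cells, 8 passed for DC and 12 for DE. Among these were erythroid-like cells in DC (-0.60, adjusted p = 0.0436) and stem and multipotent-like cells in DE (-0.73, adjusted p = 0.0289). The erythroid call was lost with another hashtag rule (-0.53). It was also lost without WT mouse 3, DC mouse 1, 2 or 3 and DE mouse 2 (-0.32, -0.57, -0.64, -0.61 and -0.60). The stem call was lost without WT mouse 1 or 2 and DE mouse 2 or 3 (-0.67, -0.73, -0.73 and -0.64). The stem and multipotent-like share in DC (-0.54, adjusted p = 0.112) and the lymphoid progenitor-like shares (0.06 and -0.04) and eosinophil-like shares (0.03 and 0.03) did not pass. The lymphoid progenitor-like share in DE passed, as a fall, with classes from the WT library alone (-0.95, adjusted p = 0.00234) and at the lower resolution (-1.22, adjusted p = 0.00369). The stem share in DC passed with classes from the WT library alone (-0.60, adjusted p = 0.0338) and without DC mouse 1 (-0.79, adjusted p = 0.0260). When the shares were scaled by TMM, which assumes that most classes keep their level, the megakaryocyte-like fall in DC (-0.52), the basophil (-0.26) and stem (-0.32) falls in DE, the erythroid fall in DC (-0.07) and the falls of the unnamed cells in DC (-0.14) and DE (-0.35) no longer passed. The rise of T, NK and innate lymphoid-like cells in DC then passed (0.89, adjusted p = 0.0111).

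**Figure D2:**
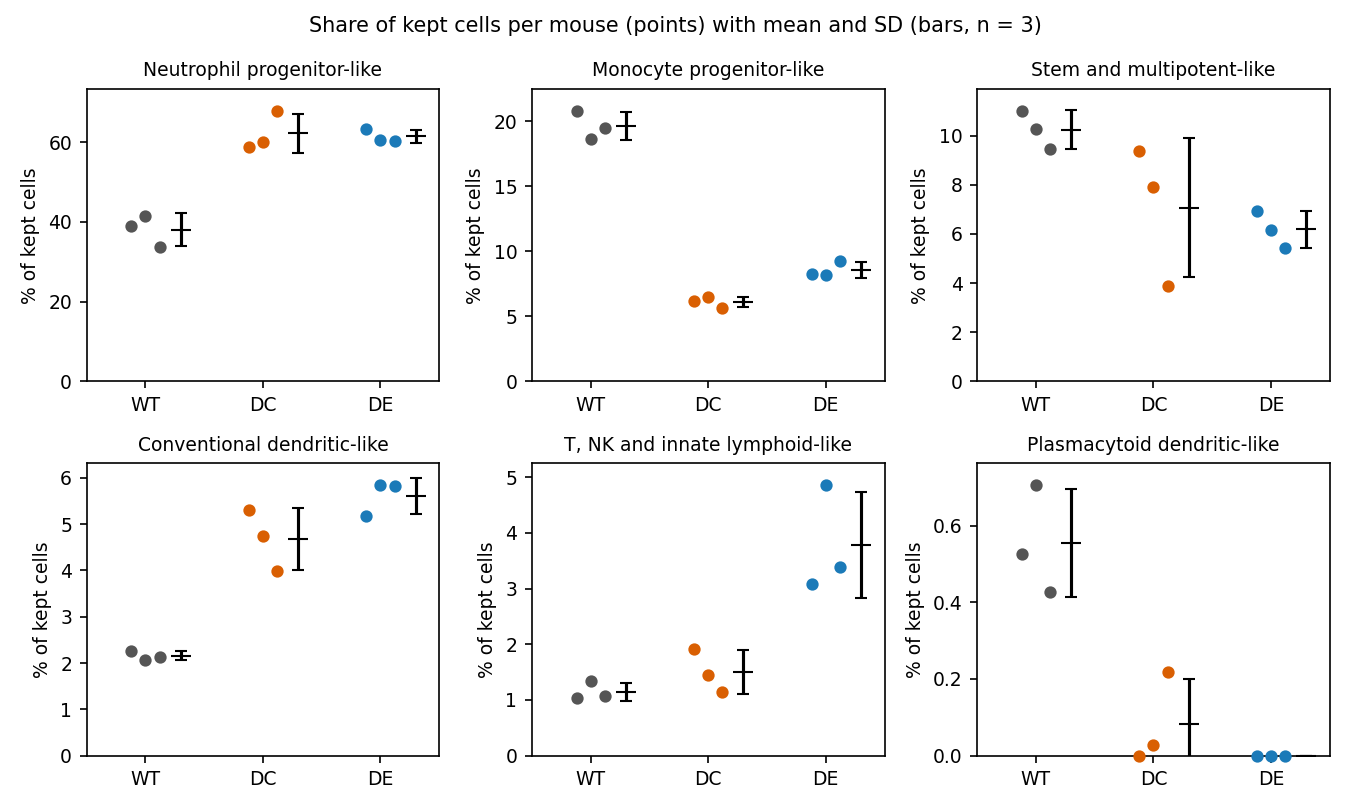
Share of each class among the kept cells of a mouse (percent, linear axis from 0) for 6 classes in WT, DC and DE; points are single mice, and the line with error bar beside them is their mean with SD. Monocyte-like cells made up 19.6% of WT, 6.10% of DC and 8.56% of DE cells, and cDC-like cells 2.16%, 4.68% and 5.62%.

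The title of the series names the specification of cDC1, the dendritic cells that express Xcr1 and Clec9a and cross-present antigen, so the dendritic classes were clustered once more on their own into 10 subclusters. The subcluster led by Cadm1, Xcr1 and Clec9a, genes of cDC1, held 0.0962 ± 0.0556% of WT cells, 0.329 ± 0.0461% of DC cells and 0.438 ± 0.0334% of DE cells (log2 fold changes 1.75 ± 0.38 and 2.16 ± 0.34, adjusted p = 0.00175 and 0.000124). A subcluster led by Tox, Il18r1 and Cd7, genes shared with lymphoid cells, rose from 0.297 ± 0.0878% to 0.691 ± 0.0867% in DE (1.21 ± 0.24, adjusted p = 0.000382). At 0.394 ± 0.0335% in DC it did not pass (adjusted p = 0.264). In all, 7 subclusters passed for DC and 8 for DE. Subcluster 6, led within the dendritic cells by Hmgcs1, Tspoap1 and Msmo1, lost its call in DE without WT mouse 3 (0.75) and without DE mouse 3 (0.90). The subcluster led by S100a8, S100a9 and Ltf, which also passed, is not read as a type of cell, because these genes differed between the genotypes within the class. The subclusters are small (101 cells in the one led by Xcr1, 11 of them WT).

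**Figure D3:**
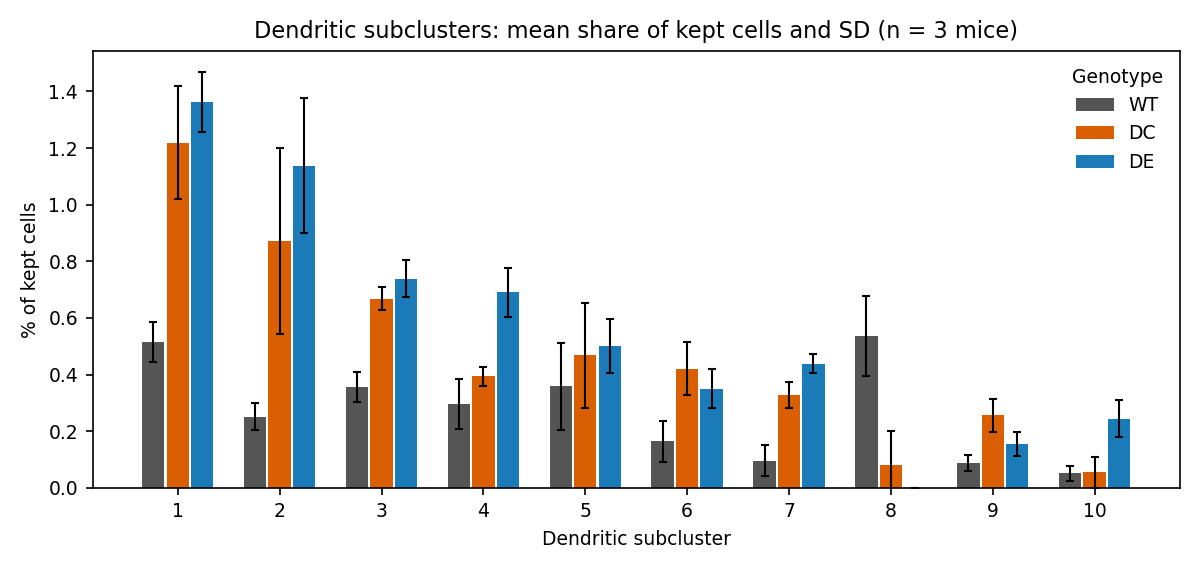
Share of each of the 10 dendritic subclusters among all kept cells (percent, linear axis from 0) for WT, DC and DE; bars are means of 3 mice and error bars are SD. Subcluster 7, led by Cadm1, Xcr1 and Clec9a, held 0.0962% of WT, 0.329% of DC and 0.438% of DE cells, and subcluster 8, the pDC-like cells, 0.536%, 0.0818% and 0%.

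Gene expression was then compared within classes, DC against WT first. In the monocyte-like class of DC, genes of monocytes were lower and genes of neutrophils, together with Id2, were higher than in WT. Id2, which encodes an inhibitor of E-protein transcription factors, rose from 9.83 ± 1.16 to 118 ± 8.05 CPM (log2 fold change 3.61 ± 0.10, adjusted p = 2.88e-13). Id1, another such inhibitor, fell from 25.9 ± 0.957 to 3.28 ± 1.19 CPM (-2.93 ± 0.15, adjusted p = 3.44e-12). Ccr2, the chemokine receptor by which monocytes leave the marrow, fell from 189.6 ± 10.8 to 22.5 ± 7.17 CPM (-3.07 ± 0.18, adjusted p = 7.72e-06). F13a1, which encodes the A chain of coagulation factor XIII, fell from 1239 ± 97.5 to 122 ± 48.3 (-3.33 ± 0.32, adjusted p = 0.000236). S100a4 fell from 155 ± 0.319 to 8.50 ± 1.97 (-4.16 ± 0.10, adjusted p = 2.66e-15). S100a9, a calcium-binding protein of neutrophils, rose from 562 ± 119 to 5698 ± 615 CPM (3.36 ± 0.22, adjusted p = 3.33e-05). Cd24a rose from 79.5 ± 4.76 to 327 ± 12.9 (2.06 ± 0.06, adjusted p = 2.53e-16).

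Among the largest changes in this class, Ptprr, a receptor tyrosine phosphatase, went from 0.609 ± 0.117 to 96.6 ± 2.96 CPM (7.30 ± 0.13, adjusted p = 7.72e-19). Batf3, a transcription factor of cDC1, went from 0.334 ± 0.181 to 1.58 ± 0.720 (2.28 ± 0.47, adjusted p = 0.000497). Lgi1 and Prss2 had no UMI in WT and were at least 54.4-fold and 34.8-fold higher in DC, against 3 UMIs over the WT group. Of the Neutrophil list 13 of 15 measured genes rose and none fell, also 13 adjusted over the list alone (camera adjusted p = 4.26e-16). Of the cDC2 list 11 of 14 fell and none rose, also 11 adjusted over the list alone (camera adjusted p = 3.55e-11; adjusted p = 0.0507 with an estimated correlation). Of the Monocyte list 12 of 16 fell and 1 rose, with 12 and 2 adjusted over the list alone (camera adjusted p = 3.37e-10; adjusted p = 0.0854 with an estimated correlation). The Interferon-stimulated (8 of 12 lower), Cell cycle G2/M (12 of 15 lower) and Dissociation and stress (9 of 14 higher) lists passed as well, with adjusted p of 0.480, 0.561 and 0.583 with an estimated correlation. Adjusted over the list alone the counts were 8, 13 and 10. Other splits of the 6 mice compared passed as many lists in every class for DC minus WT, and in monocyte- and neutrophil-like cells for other contrasts. There the number of lists cannot separate a genotype effect from none, because the splits are too few and each keeps part of the difference. The E proteins and inhibitors list did not pass (1 higher, 2 lower of 5; adjusted p = 0.927). Tcf4, which encodes an E protein, was lower (130 ± 15.6 to 91.4 ± 2.93 CPM, -0.48 ± 0.08), and Tcf3 and Tcf12 did not pass. Of the Dendritic transcription factors list 5 rose and 7 fell among 17 (adjusted p = 0.459). Zeb2os, the antisense partner of Zeb2, was lower (-1.99 ± 0.09), a value uncertain because whether counting used strand is not given.

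In all 5609 of 12667 genes differed in this class (2759 higher, 2850 lower; 1276 by over 2-fold). The mice of DC and WT did not overlap for 52.7% of genes, where chance gives 10%. The class was filled by different clusters in the genotypes: clusters 19, 27 and 33 held 38.9%, 24.9% and 17.9% of it in WT, and clusters 21 and 29 held 50.7% and 35.2% in DC. Of the Monocyte list 9 genes, and all 15 of the Neutrophil list, are also markers by which classes were named, Mcpt8 as a marker of the basophil and mast class. In cluster 31, the only one to which each genotype gave at least 10% of cells, 704 genes differed. It held 14.5%, 10.8% and 9.30% of the class in WT, DC and DE. There S100a4 was at -1.78, F13a1 at -1.33, Ccr2 at -2.21, Cd24a at 1.33, S100a9 at 1.05, Ptprr at 3.93 and Tcf4, no longer past the test, at -0.05. With classes from the WT library alone 4750 genes differed, and after thinning 2473. S100a9 was at 2.19 where only cells with several hashtags were removed.

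In the cDC-like class of DC, Id2, Rab7b, Ifi205 and Gcsam, members of the cDC1 list, were higher and Cd209a, a C-type lectin used as a cDC2 marker, was lower. Id2 went from 959 ± 77.4 to 1283 ± 50.3 CPM (log2 fold change 0.39 ± 0.06, adjusted p = 5.72e-05), Rab7b from 160 ± 19.0 to 250.1 ± 26.9 (0.61 ± 0.09) and Ifi205 from 262 ± 13.4 to 394 ± 28.9 (0.55 ± 0.08). Gcsam rose from 21.6 ± 5.79 to 51.7 ± 6.90 (1.22 ± 0.21, adjusted p = 0.00056). Cd209a fell from 53.1 ± 21.6 to 0.983 ± 0.904 CPM (-5.62 ± 0.51, adjusted p = 1.41e-05; -6.32 without DC mouse 1 and -4.37 after thinning). Of the cDC1 list 7 of 19 genes rose and none fell, 8 adjusted over the list alone (camera adjusted p = 1.11e-12; adjusted p = 0.184 with an estimated correlation). Of that list 7 genes are also class markers, Irf8 as one of the monocyte class. Cluster 38, with Cadm1, Clec9a and Xcr1 among its leading genes, held 5.65% of the class in WT, 12.1% in DC and 11.8% in DE. In cluster 7, the only one shared by the genotypes, these 4 cDC1 genes and Cd209a still passed in DC. Of the cDC2 list 2 of 14 fell and none rose, with 6 lower and 3 higher adjusted over the list alone (camera adjusted p = 1.23e-06; adjusted p = 0.0519 with an estimated correlation).

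The immediate early genes Egr1 (26.0 ± 11.5 to 105 ± 3.9999 CPM, 1.99 ± 0.18) and Dusp1 (122 ± 16.5 to 273 ± 21.0, 1.12 ± 0.10) rose in cDC-like cells of DC. They were among 7 of 13 measured genes of the Dissociation and stress list that rose, 10 adjusted over the list alone (camera adjusted p = 6.11e-26). Of the Neutrophil list 7 of 14 rose and 1 fell, 8 and 1 adjusted over the list alone (camera adjusted p = 3.74e-15). The summed level of that list also rose in erythroid-like cells, from 1109 ± 291 CPM in WT to 2342 ± 148 in DC and 3201 ± 291 in DE, beside 1442 ± 38.7, 3760 ± 919 and 2612 ± 257 in cDC-like cells. The Monocyte (2 lower, 1 higher of 15), Cell cycle G2/M (1 higher) and Erythroid (1 lower of 6) lists passed with adjusted p of 0.0451, 0.0362 and 0.0159, and 0.600, 0.671 and 0.184 with an estimated correlation. Adjusted over the list alone these were 5 lower and 5 higher, 1 higher, and 1 lower. The MHC class II list did not pass (0 of 10 genes; adjusted p = 0.866). In all 371 of 10420 genes differed (249 higher, 122 lower), 236 without DC mouse 2 and 206 after thinning. Mice did not overlap for 19.2% of genes, against 10% by chance, and 33.3% of simulated changes of 0.5 on the log2 scale were found in this class.

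In the stem and multipotent-like class of DC, Dntt, Flt3, Mcpt8 and Id2 were higher and Id1 and Ms4a6c lower than in WT. Dntt, which encodes the template-independent DNA polymerase of lymphocyte receptor rearrangement, rose from 57.7 ± 6.22 to 114 ± 11.1 CPM (log2 fold change 0.99 ± 0.09, adjusted p = 3.38e-07). Flt3, a cytokine receptor of lymphoid and dendritic progenitors, rose from 163 ± 4.11 to 232 ± 15.4 (0.52 ± 0.10, adjusted p = 0.00254). Mcpt8, a basophil protease that is also a member of the Neutrophil list, rose from 32.7 ± 6.63 to 199.8 ± 52.1 (2.64 ± 0.24, adjusted p = 0.00142). Id2 rose from 4.77 ± 0.280 to 19.999 ± 3.10 CPM (2.08 ± 0.17, adjusted p = 1.45e-07; 1.29 after thinning). Id1 fell from 5.54 ± 0.840 to 1.38 ± 0.114 (-1.96 ± 0.33, adjusted p = 0.000806). Ms4a6c, a myeloid membrane protein, fell from 80.4 ± 4.12 to 40.5 ± 11.3 (-0.93 ± 0.16, adjusted p = 0.00636).

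The cDC1 list passed in this class (3 of 9 higher, 4 adjusted over the list alone; camera adjusted p = 1.03e-05; adjusted p = 0.0494 with an estimated correlation). The Neutrophil list passed as well (8 of 15 higher, with 9 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.89e-22; adjusted p = 0.0219 with an estimated correlation), beside its summed level of 6934 ± 315 CPM in WT, 8565 ± 1195 in DC and 7349 ± 459 in DE. Ngp, Lcn2 and S100a9 lost the call with only cells with several hashtags removed. Of the Early lymphoid list 3 of 7 and of the pDC list 3 of 11 rose, 4 and 5 adjusted over the list alone. Both passed with the preset correlation (adjusted p = 3.82e-05 and 0.000584; 0.0618 and 0.163 with an estimated correlation). So did Cell cycle G2/M (4 of 15 lower, 10 adjusted over the list alone) and Dissociation and stress (0 of 14, 2 higher adjusted over the list alone). Both had adjusted p = 6.62e-06, and 0.275 and 0.309 with an estimated correlation. In all 877 of 12513 genes differed (559 higher, 318 lower), 527 without DC mouse 1, 459 without DC mouse 2 and 347 after thinning. Mice did not overlap for 26.4% of genes, against 10% by chance.

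In the neutrophil-like class of DC, F13a1, Mgl2 and Irf8 were lower and Ngp and Id2 higher than in WT. F13a1 fell from 46.4 ± 6.82 to 0.510 ± 0.0722 CPM (log2 fold change -6.52 ± 0.30, adjusted p = 1.98e-06; -5.74 with classes from the WT library alone). It also fell in erythroid-like cells (-4.41), so less free RNA or fewer doublets of monocyte-like cells may account for it. Mgl2, a macrophage galactose-type lectin, fell from 38.7 ± 2.43 to 5.98 ± 0.383 (-2.71 ± 0.09, adjusted p = 1.47e-11). Irf8, a transcription factor of monocytes and dendritic cells, fell from 11.97 ± 1.30 to 4.90 ± 0.622 (-1.30 ± 0.11, adjusted p = 3.10e-07; -0.24 with classes from the WT library alone). Ngp, a granule protein, rose from 11217 ± 463 to 18969.7 ± 1963 CPM (0.74 ± 0.07, adjusted p = 9.85e-06). Ctsg, the protease cathepsin G, fell from 3525 ± 179.6 to 2194 ± 245 (-0.70 ± 0.10, adjusted p = 0.000323). Id2 rose from 85.4 ± 1.52 to 196 ± 2.91 (1.17 ± 0.06, adjusted p = 4.99e-09). The Dissociation and stress list passed (11 of 14 higher, 12 adjusted over the list alone; camera adjusted p = 1.19e-07; adjusted p = 0.612 with an estimated correlation), with Fos at 61.4 ± 17.8 in WT and 179 ± 30.2 CPM in DC. The Mitochondrially encoded list passed too (10 of 13 lower, 10 adjusted over the list alone; adjusted p = 0.0414, and 0.792 with an estimated correlation). Lists past the test went from 2 to 1 without WT mouse 1 or 3, DC mouse 1 or 2, or DE mouse 1 or 2, and to 5 without WT mouse 2. The Neutrophil list did not (9 higher, 5 lower; adjusted p = 0.0761), nor did the Monocyte list (5 higher, 6 lower of 15, and 6 and 6 adjusted over the list alone; adjusted p = 0.158), whose median log2 fold change of 0.04 and mean of -1.02 differed in sign. In all 7051 of 14385 genes differed (3395 higher, 3656 lower; 972 by over 2-fold), 4605 after thinning. Mice did not overlap for 56.8% of genes, against 10% by chance. Cluster 10 held 21.5% of this class in WT and 1.44% in DC, and cluster 8 0.501% and 10.3%.

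DE was compared with WT in the same classes. In the monocyte-like class of DE, Id2 was higher at 43.6 ± 6.01 CPM (log2 fold change 2.17 ± 0.11, adjusted p = 4.48e-10; 3.23 in cluster 31) and Id1 lower at 8.93 ± 0.138 (-1.51 ± 0.11, adjusted p = 3.37e-09). Ccr2 fell to 82.1 ± 7.57 CPM (-1.19 ± 0.15, adjusted p = 0.000812) and Csf1r, the receptor of the macrophage growth factor, from 75.5 ± 8.98 to 34.5 ± 5.88 (-1.11 ± 0.13, adjusted p = 0.000108). S100a4 fell to 46.9 ± 4.32 (-1.71 ± 0.08, adjusted p = 2.22e-11). Cebpe, a transcription factor of granulocytes, rose from 10.5 ± 1.43 to 53.4 ± 6.64 CPM (2.36 ± 0.10, adjusted p = 3.89e-11) and Cd24a to 251 ± 6.18 (1.68 ± 0.05). Cd6, a receptor of lymphocytes, went from 0.362 ± 0.174 to 18.5 ± 1.05 CPM (5.68 ± 0.18, adjusted p = 6.17e-15).

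Of the Neutrophil list 12 of 15 genes rose in monocyte-like cells of DE, 13 adjusted over the list alone (camera adjusted p = 5.64e-16). Of the Interferon-stimulated list 10 of 12 fell, also 10 adjusted over the list alone (camera adjusted p = 6.00e-06; adjusted p = 0.166 with an estimated correlation). The cDC1 (6 of 12 higher, 2 lower), cDC2 (7 of 14 lower) and Monocyte (9 of 16 lower, 1 higher) lists passed. Adjusted p was 0.000314, 4.64e-05 and 0.00037, and 0.0661, 0.134 and 0.227 with an estimated correlation. Adjusted over the list alone the counts were 6 and 3, 7, and 10 and 1. Cell cycle G2/M (9 lower), Dissociation and stress (5 higher), Erythroid (3 of 9 lower) and Mitochondrially encoded (6 lower, 1 higher) passed too, with adjusted p of 0.552, 0.552, 0.0759 and 0.552 with an estimated correlation. Adjusted over the list alone these were 9 lower, 7 higher, 6 lower, and 7 lower and 2 higher. In all 4138 genes differed (2127 higher, 2011 lower; 718 by over 2-fold). Mice did not overlap for 46.0% of genes, against 10% by chance. Clusters 21 and 29 held 43.5% and 28.7% of the class in DE. In cluster 31 alone 675 genes differed, and 1749 in the class after thinning.

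In the cDC-like class of DE, Cd209a was lower at 8.13 ± 2.69 CPM (log2 fold change -2.70 ± 0.34, adjusted p = 0.000334). Rab7b (224 ± 8.29 CPM, 0.46 ± 0.09, adjusted p = 0.00293), Egr1 (83.7 ± 9.90 CPM, 1.67 ± 0.18) and Dusp1 (298 ± 31.4 CPM, 1.255 ± 0.10) were higher than in WT. Of the cDC1 list 6 of 19 genes rose and none fell, 6 adjusted over the list alone (camera adjusted p = 4.30e-06; adjusted p = 0.341 with an estimated correlation). The Dissociation and stress (6 of 13 higher), Neutrophil (4 of 14 higher) and Interferon-stimulated (3 of 9 lower) lists passed. Adjusted p was 8.89e-22, 3.06e-06 and 4.30e-06, and 0.0601, 0.119 and 0.0601 with an estimated correlation. Adjusted over the list alone the counts were 9 higher, 7 higher and 1 lower, and 3 lower. The cDC2 (2 lower, 1 higher of 14), Cell cycle S (1 higher of 15), Erythroid (1 lower of 6) and Mitochondrially encoded (4 lower of 13) lists passed as well, with adjusted p of 0.303, 0.436, 0.125 and 0.352 with an estimated correlation. Adjusted over the list alone these were 2 lower and 1 higher, 2 higher, 2 lower and 4 lower. In all 443 genes differed (242 higher, 201 lower), 262 without DE mouse 1, 279 without DE mouse 2 and 231 after thinning. Mice did not overlap for 21.4% of genes, against 10% by chance.

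In the stem and multipotent-like class of DE, Dntt rose to 134 ± 5.81 CPM (log2 fold change 1.23 ± 0.08, adjusted p = 1.19e-08) and Flt3 to 227 ± 36.6 (0.50 ± 0.09). Mcpt8 rose to 141 ± 14.9 (2.13 ± 0.24, adjusted p = 0.00331). Ms4a6c fell to 37.8 ± 6.71 (-1.08 ± 0.16). The cDC1 (4 of 9 higher), Neutrophil (6 of 15 higher), Early lymphoid (3 of 7 higher) and Interferon-stimulated (5 of 14 lower) lists passed, with adjusted p of 0.000407, 1.17e-06, 0.000327 and 1.27e-05. They had adjusted p of 0.126, 0.126, 0.126 and 0.279 with an estimated correlation. Adjusted over the list alone these were 4 higher, 8 higher and 1 lower, 4 higher, and 7 lower. The Monocyte (4 lower), Cell cycle S (0), Dissociation and stress (0) and Mitochondrially encoded (5 lower) lists passed with the preset correlation. They had adjusted p of 0.396, 0.501, 0.501 and 0.396 with an estimated correlation. Adjusted over the list alone 5, 0, 0 and 6 of their genes passed. In all 1342 genes differed (771 higher, 571 lower), 771 without WT mouse 2, 600 without DE mouse 1, 603 without DE mouse 2, 591 after thinning and 893 by DESeq2. Mice did not overlap for 27.0% of genes, against 10% by chance.

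In the neutrophil-like class of DE, F13a1 (3.46 ± 1.33 CPM, log2 fold change -3.76 ± 0.23, adjusted p = 5.10e-06) and Mgl2 (7.32 ± 0.848 CPM, -2.42 ± 0.08, adjusted p = 3.71e-11) were lower than in WT. Id2 (181 ± 19.5 CPM, 1.06 ± 0.06), Ngp (20718 ± 1063 CPM, 0.87 ± 0.07) and Camp, the antimicrobial peptide cathelicidin (19383 ± 1003 to 34569 ± 2394 CPM, 0.82 ± 0.05), were higher. The MHC class II genes Cd74 (1.29 ± 0.231 to 4.72 ± 0.0990 CPM) and H2-Aa (1.04 ± 0.311 to 3.93 ± 0.396 CPM) rose by 1.84 ± 0.14 and 1.88 ± 0.18. The MHC class II list did not pass (4 higher, 2 lower of 9, and 4 and 3 adjusted over the list alone; adjusted p = 0.324). The Mitochondrially encoded (13 of 13 lower) and Dissociation and stress lists (6 higher, 5 adjusted over the list alone) passed. Adjusted p was 1.61e-06 and 0.0152, and 0.682 for both with an estimated correlation. In all 7996 genes differed (3908 higher, 4088 lower; 954 by over 2-fold). Mice did not overlap for 62.9% of genes, against 10% by chance. Cluster 10 held 1.35% of the class in DE.

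The last comparison set DE against DC, the 2 variants. In the monocyte-like class F13a1, Clec4a3 and Id1 were higher and Cebpe and Id2 lower in DE. F13a1 was higher in DE than in DC (625 ± 139 and 122 ± 48.3 CPM, log2 fold change 2.36 ± 0.31, adjusted p = 0.00445; 1.20 in cluster 31). Clec4a3, a C-type lectin of myeloid cells, was higher at 3.42 ± 0.685 and 0.164 ± 0.0545 CPM (4.27 ± 0.49, adjusted p = 7.60e-06), as was Id1 (1.41 ± 0.17, adjusted p = 1.76e-05). Cebpe was lower (-0.76 ± 0.09, adjusted p = 3.63e-05), as was Id2 (-1.44 ± 0.09, adjusted p = 8.68e-08), which in cluster 31 no longer passed (-0.65, adjusted p = 0.128). Of the Monocyte list 11 of 16 and of the cDC2 list 10 of 14 genes were higher and none lower, 11 each adjusted over the list alone (camera adjusted p = 5.40e-19 and 6.98e-19). Of the Neutrophil list 8 of 15 were lower and none higher, 10 and 1 adjusted over the list alone (camera adjusted p = 1.46e-08). The MHC class II list (2 of 9 higher; 2 higher and 1 lower adjusted over the list alone) and the Zeb2 neighbours on the chromosome (2 of 7 higher, Zeb2os among them) passed with adjusted p of 0.431 and 0.241 with an estimated correlation. In all 1550 genes differed (846 higher, 704 lower; 243 by over 2-fold), 567 after thinning and 36 in cluster 31 alone. The class differed in makeup here too: clusters 19, 27, 33 and 40 held 7.21%, 2.75%, 4.08% and 4.46% of it in DE, and 0.2999%, 1.499%, 0.450% and 1.05% in DC. Mice did not overlap for 31.7% of genes, against 10% by chance.

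In cDC-like cells Il18r1, the interleukin 18 receptor, was higher in DE (19.0 ± 4.71 to 52.4 ± 4.99 CPM, log2 fold change 1.46 ± 0.21, adjusted p = 0.00165). In all 217 genes differed (75 higher, 142 lower), 85 after thinning, 391 with no filter on low counts and 380 with only the 6 mice compared. The number was 107, 108, 87, 84 and 107 without DC mouse 1 or 2 or DE mouse 1, 2 or 3. Of the Interferon-stimulated list 5 of 9 were lower, 5 adjusted over the list alone (camera adjusted p = 2.62e-10). The cDC1 (1 of 19 lower, 6 adjusted over the list alone), cDC2 (1 higher), Neutrophil (1 lower), Early lymphoid (1 of 6 higher), Cell cycle G2/M (1 lower, 8 adjusted over the list alone) and Zeb2 neighbour (1 higher) lists passed, with adjusted p of 0.642 for cDC1 and 0.131 for each of the others with an estimated correlation. In stem and multipotent-like cells Wdfy1 (18.9 ± 0.0899 to 50.4 ± 2.70 CPM, 1.42 ± 0.10, adjusted p = 3.72e-08) was higher. In all 34 genes differed (9 higher, 25 lower), 22 without DE mouse 1, 70 without DE mouse 3, 149 with no filter on low counts and 59 by DESeq2. There 8 lists passed with the preset correlation, among them pDC, MHC class II, Cell cycle S and Interferon-stimulated (adjusted p = 0.0200, 0.0200, 0.0200 and 8.86e-09), and none with an estimated correlation (lowest adjusted p = 0.148). In neutrophil-like cells 1365 genes differed (731 higher, 634 lower), and 884 after thinning. The number was 369, 183, 3093, 188 and 264 without DC mouse 1, 2 or 3 or DE mouse 1 or 2. Of 7 lists that passed, Mitochondrially encoded had the lowest adjusted p (2.45e-10; 0.255 with an estimated correlation). Mice did not overlap for 20.7%, 14.4% and 30.2% of genes in these 3 classes, where chance gives 10%.

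Of the shares, monocyte-like cells were higher in DE than in DC (1.40-fold, log2 fold change 0.49 ± 0.14, adjusted p = 0.0206). The call was lost without DE mouse 1 (0.51, adjusted p = 0.0516) or 3 (0.43, adjusted p = 0.107) and under TMM scaling (0.40, adjusted p = 0.104). T, NK and innate lymphoid-like cells were 2.51-fold higher in DE (1.33 ± 0.25, adjusted p = 0.00228). DC was at least 7.15-fold and 19.9-fold above the limit of DE for B lineage-like and plasma cell-like cells (adjusted p = 0.00521 and 0.00228). Calls were gained for pDC-like cells at the lower resolution (-5.34) and without DC mouse 1 (-5.30), and for megakaryocyte-like (-0.72) and stem and multipotent-like cells (-0.48) without DC mouse 3. cDC-like cells did not pass (0.26 ± 0.16, adjusted p = 0.230), nor did the dendritic subcluster led by Xcr1 (0.41 ± 0.26, adjusted p = 0.304). The 2 dendritic subclusters that passed, led by Tox (0.80, adjusted p = 0.0194) and by Auts2 (2.08, adjusted p = 0.0194), both failed without DC mouse 2 (0.74 and 1.52) and without DE mouse 3 (0.73 and 1.98). The first also failed without DE mouse 2 (0.77). The second failed without DE mouse 1 (1.95) and was 3.00 without DC mouse 3.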

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

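The tests of the monocyte-like share, of lymphoid Zeb2, of UMIs per cell and in single shared clusters were chosen after the result was seen, and the test of the Neutrophil list in CPM before.

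The change in Zeb2 differed between some classes when tested against the change in the stem and multipotent-like class (log2 differences from edgeR's quasi-likelihood test of the interaction, with adjusted p over all genes, 3 mice per genotype). In the neutrophil-like class the difference was -2.95 for DC minus WT (adjusted p = 2.05e-12), -1.40 for DE minus WT (adjusted p = 2.02e-08) and 1.56 for DE minus DC (adjusted p = 1.63e-06). The share of DC cells with a Zeb2 UMI in that class (1.99 to 2.73%) was not distinguishable from background. That of DE (5.91 to 7.05%) lay above that of DC and within the background intervals of WT (0.636 to 8.69%) and DC (1.21 to 15.9%), with none measured in DE. The monocyte-like class differed by -0.92, 0.68 and 1.60 (adjusted p = 1.07e-11, 7.40e-09 and 1.60e-16). Different clusters filled that class in the genotypes, and in cluster 31, the only one shared (328 WT, 72 DC and 98 DE cells), it differed by -0.34, 0.30 and 0.64, of which only the last passed (adjusted p = 0.0984, 0.125 and 0.00511). The lymphoid progenitor-like class lay 1.15 above for DC minus WT (adjusted p = 0.00368) and at -1.25 for DE minus DC (adjusted p = 0.0449). The T, NK and innate lymphoid-like class lay at 1.52 (adjusted p = 4.77e-06) and -1.19 (adjusted p = 0.000701). Cluster 35 held 14.4%, 20.7% and 45.3% of that class in WT, DC and DE, and without it, in the shared cluster, the values were 1.65 (adjusted p = 4.60e-08) and -0.90 (adjusted p = 0.0288). The megakaryocyte-like class differed by 1.72 for DC minus WT (adjusted p = 1.08e-14) and 1.30 for DE minus WT (adjusted p = 1.74e-11). The erythroid-like class differed by 1.71 (adjusted p = 9.85e-10) and 1.43 (adjusted p = 1.43e-08). DE minus DC did not pass in these (-0.42 and -0.29, adjusted p = 0.135 and 0.586), nor DE minus WT in the lymphoid progenitor-like (-0.10) and T, NK and innate lymphoid-like (0.33) classes (adjusted p = 0.879 and 0.687). No contrast passed in the basophil and mast-like (-0.0019, 0.32 and 0.33, adjusted p = 0.9995, 0.127 and 0.512) and cDC-like classes (-0.09, 1.21 and 1.30, adjusted p = 0.982, 0.473 and 0.634).

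Monocyte-like cells were a smaller share in both variants, while neutrophil-like cells were a larger one. The class pools clusters that moved in opposite directions, such as cluster 19 (7.64% of WT, 0.0182% of DC and 0.619% of DE cells) and cluster 21 (0.0597%, 3.09% and 3.73%). Among the cells outside the neutrophil-like class the monocyte-like share was 31.8 ± 2.43% in WT (29.3 to 34.2%), 16.3 ± 1.35% in DC and 22.2 ± 1.30% in DE, which argues against dilution by neutrophil-like cells as the whole cause. With 1 library per genotype, a difference between libraries cannot be told apart from one between genotypes. The genotype stays open, as untested apart from the library.

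Genes of the Neutrophil list, abundant transcripts of neutrophil-like cells, were higher in other classes of the variants. The rise of the summed list over its mean rise in the erythroid and megakaryocyte-like classes was 1.65 (DC) and 0.337 (DE) in stem and multipotent-like cells and 2.34 (DC) and 0.951 (DE) in cDC-like cells in CPM, and 1.10, 0.401, 1.02 and 0.444 in UMIs per cell. A ratio of up to 2 was set as what free RNA gives, and only 2.34 lay over it. The classes averaged differ, rising by 62.98 (DC) and 79.96 (DE) UMIs per cell (erythroid) and 16.99 and 10.26 (megakaryocyte). Their mean therefore cannot decide, and free RNA from the larger neutrophil-like share stays open. With only cells with several hashtags removed, calls were lost in stem and multipotent-like cells for Ngp (2.03 to 0.84, adjusted p = 0.164), Lcn2 (1.94 to 0.81) and S100a9 (1.82 to 1.16) in DC and for Ngp (1.41 to 0.58), Ltf and Lcn2 in DE, so the treatment of doublets stays open too. No biological explanation was tested.

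In lymphoid progenitor-like cells Zeb2 was lower in DE than in DC, against the order in the neutrophil- and monocyte-like classes. In thinned cells the log2 fold change was -1.60, which argues against depth. With its 2 clusters weighted alike, the share of thinned cells with a Zeb2 UMI differed by -37.1 percentage points (67.2% in DC and 32.9% in DE in one cluster, 61.2% and 20.5% in the other), which argues against a different makeup of the class. A class-specific action of the DE variant is a hypothesis, and a difference between libraries (1 per genotype) cannot be told apart from it.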

How the results depend on the processing

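The restriction to the cluster shared by the genotypes, and the block and left-out mice for gene lists, were chosen after the data were seen. Over the alternatives, single named genes kept their direction and side of the threshold in 12854 comparisons, lost the call in 1544 and turned in 24. Shares of single classes did so in 611, 21 and 30, with 10 calls gained. The falls of Zeb2 over all cells and in the neutrophil-, monocyte-, and stem and multipotent-like classes against WT kept direction and call in every alternative run. The cause was not tested for the values that follow.

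Thinning, which leaves fewer UMIs, gave fewer changed genes (DC minus WT, DE minus WT and DE minus DC): 2473, 1749 and 567 in the monocyte-like class and 206, 231 and 85 in the cDC-like class. It gave 347 and 591 for the first pair of contrasts in the stem and multipotent-like class, and 4605 (DC minus WT) and 884 (DE minus DC) in the neutrophil-like class. In cluster 31, the only monocyte-like one shared by the genotypes (14.5%, 10.8% and 9.30% of the class), the numbers were 704, 675 and 36. DE minus DC in the stem and multipotent-like class gave 52 genes with classes from WT alone, 149 with no filter on low counts and 59 by DESeq2. For DE minus WT DESeq2 gave 893. In the cDC-like class no filter gave 570 (DC minus WT) and 391 (DE minus DC), and a fit of only the 6 mice compared 380 (DE minus DC). The larger monocyte-like share in DE than in DC (0.40, adjusted p = 0.104) was lost with TMM over classes in edgeR.

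With an estimated correlation in camera, fewer gene lists passed (DC minus WT, DE minus WT and DE minus DC): 2, 0 and 0 in the stem and multipotent-like class, 0, 0 and 0 in the neutrophil-like class, 1, 1 and 3 in the monocyte-like class and 2, 0 and 1 in the cDC-like class.

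Each mouse was left out in turn. Changed genes in the stem and multipotent-like class numbered 459 (without DC mouse 2) to 1118 (without DE mouse 3) for DC minus WT. There DE minus WT gave 600 (without DE mouse 1) to 1885 (without DE mouse 3), and DE minus DC 22 (without DE mouse 1) to 70 (without DE mouse 3). Changed genes in the neutrophil-like class numbered 6052 (without WT mouse 1) to 6988 (without DE mouse 3) for DC minus WT. There DE minus WT gave 7052 (without DE mouse 1) to 8301 (without DC mouse 3), and DE minus DC 183 (without DC mouse 2) to 3093 (without DC mouse 3). Changed genes in the monocyte-like class numbered 4776 (without DC mouse 2) to 5531 (without WT mouse 2) for DC minus WT. There DE minus WT gave 3223 (without DE mouse 2) to 4248 (without DC mouse 3), and DE minus DC 1079 (without DE mouse 3) to 1882 (without WT mouse 2). Changed genes in the cDC-like class numbered 236 (without DC mouse 2) to 368 (without WT mouse 1) for DC minus WT. There DE minus WT gave 262 (without DE mouse 1) to 446 (without DC mouse 3), and DE minus DC 84 (without DE mouse 2) to 273 (without WT mouse 1). Gene lists past the threshold ran (same order of contrasts) from 6 to 9, 6 to 10 and 4 (without DC mouse 2) to 8 (without WT mouse 1) in the stem and multipotent-like class. They ran from 1 (without WT mouse 1) to 5 (without WT mouse 2), 1 (without WT mouse 3) to 2 (without WT mouse 1) and 4 (without DC mouse 3) to 10 (without DC mouse 1) in the neutrophil-like class. They ran from 7 to 8, 9 to 9 and 5 to 6 in the monocyte-like class. They ran from 5 to 7, 8 to 10 and 6 (without DC mouse 1) to 11 (without DC mouse 3) in the cDC-like class. Class shares past the threshold ran from 7 to 8, 11 to 12 and 3 to 6. Dendritic subclusters past it ran from 7 to 8, 7 to 8 and 0 to 3. The log2 change of the monocyte-like share ran from -1.73 to -1.64, -1.26 to -1.15 and 0.43 to 0.53. Its DE minus DC call was lost without DE mouse 1 (0.51, adjusted p = 0.0516) and DE mouse 3 (0.43, adjusted p = 0.107). That of the cDC-like share ran from 1.02 to 1.22, 1.35 to 1.44 and 0.16 to 0.36. Zeb2 over all cells ran from -2.16 to -2.07, -1.53 to -1.45 and 0.58 to 0.66. In the cDC-like class, where it passed in no contrast, it ran from -2.39 to -1.38, -0.80 to 0.11 and 1.22 to 2.02.

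The log2 fold changes of these genes turned direction. In cluster 31 of the monocyte-like class they were Atp1b1 (-1.44), Upb1 (0.99), Gins2 (0.11), Rrm1 (0.016), Aurkb (0.044), Cenpf (0.086), Nusap1 (0.36) and Ier3 (-0.98) for DC minus WT. For DE minus WT they were Gins2 (0.11), Rrm1 (0.0057) and Ier3 (-0.72). For DE minus DC they were Upb1 (-0.49), Rnase6 (-0.10), Runx2 (0.068), S100a9 (0.029), Gfi1 (0.019), H2-DMa (-0.11), Aurkb (-0.33) and Blvrb (-0.34). Irf8 in the neutrophil-like class (DE minus WT) was 0.10 with classes from the WT library alone. Acvr2a in the monocyte-like class (DC minus WT) was 0.13 in thinned cells. Ltf in the cDC-like class (DE minus DC) was 0.60 with only cells with several hashtags removed and 0.017 in thinned cells. Zeb2 in the cDC-like class (DE minus WT) was 0.11 without WT mouse 2. Its range reached -0.80 without WT mouse 1. Ifitm6 in the lymphoid progenitor-like class (DC minus WT) was -0.067 with only cells with several hashtags removed. Zeb2 in the T, NK and innate lymphoid-like class (DC minus WT) was 0.052 in thinned cells. Zeb2 in the megakaryocyte-like class (DC minus WT) was 0.012 with only cells with several hashtags removed, 0.080 with classes from the WT library alone, 0.079 without WT mouse 3, 0.049 without DC mouse 1 and 0.084 without DC mouse 2. Its range reached -0.18 without DC mouse 3.

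The log2 changes of these shares turned direction. Where leaving out a mouse turned one, the other end of its range is given after it, as reaching. The eosinophil-like share for DE minus DC was -0.016 with the hashtag ratio rule, -0.031 with classes from the WT library alone, -0.073 with TMM over classes, -0.034 without DC mouse 1, -0.30 without DC mouse 3, -0.050 without DE mouse 2 and -0.054 without DE mouse 3, reaching 0.44 without DC mouse 2. The eosinophil-like share for DC minus WT was -0.14 with the stricter cell filter, -0.096 without WT mouse 2, -0.12 without WT mouse 3 and -0.41 without DC mouse 2, reaching 0.34 without WT mouse 1. The eosinophil-like share for DE minus WT was -0.0071 with classes from the WT library alone, -0.091 without WT mouse 2, -0.12 without WT mouse 3, -0.024 without DE mouse 2 and -0.028 without DE mouse 3, reaching 0.34 without WT mouse 1. The lymphoid progenitor-like share for DC minus WT was -0.39 with classes from the WT library alone, -0.37 at Leiden resolution 1, -0.17 without WT mouse 3 and -0.14 without DC mouse 2, reaching 0.28 without DC mouse 1. The lymphoid progenitor-like share for DE minus WT was 0.36 with TMM over classes, 0.054 without WT mouse 1, 0.12 without WT mouse 2 and 0.065 without DE mouse 1, reaching -0.28 without WT mouse 3. The lymphoid progenitor-like share for DE minus DC was 0.095 without DC mouse 2 and 0.0021 without DE mouse 1, reaching -0.33 without DC mouse 1. The basophil and mast-like share for DC minus WT was 0.16 with TMM over classes. The stem and multipotent-like share for DE minus DC was 0.064 without DC mouse 1, reaching -0.48 without DC mouse 3. The neutrophil-like share for DE minus DC was 0.048 without DC mouse 3, reaching -0.058 without DC mouse 1. The unnamed share for DE minus DC was 0.028 without DC mouse 3, reaching -0.20 without DE mouse 1. The dendritic subcluster 10 for DC minus WT was -0.22 without WT mouse 3 and -0.85 without DC mouse 3, reaching 0.63 without DC mouse 2. The dendritic subcluster 5 for DE minus DC was -0.17 without DC mouse 3 and -0.034 without DE mouse 1, reaching 0.39 without DC mouse 1.

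The hashtag numbers were not taken to pair the mice, as not every same-number pair correlated by over 0.1 in deviations from the genotype means. Values were 0.0603 to 0.2963 (6 of 9 over 0.1), against -0.2205 to 0.1095 for other pairs. The 3 pairs of WT and DC mice were all over 0.1, up to 0.1629. Without 6 sex-linked genes these were at 0.0668 to 0.0888, and all pairs at 0.0216 to 0.2037 (3 of 9 over 0.1). WT mouse 2 and DC mouse 1 correlated best, among DE mice, with another number. With the number as a block, edgeR gave 57 changed genes in the stem and multipotent-like class for DE minus DC, 10 (DC minus WT) and 104 (DE minus DC) in the T, NK and innate lymphoid-like class and 71 (DC minus WT) in the megakaryocyte-like class, and 4 gene lists passed in the neutrophil-like class for DC minus WT. Shares that no longer passed were the monocyte-like one for DE minus DC (0.49, adjusted p = 0.0673), the pDC-like subcluster 8 for DC minus WT (-2.67, adjusted p = 0.181) and DE minus WT (-7.39, adjusted p = 0.0725) and subcluster 4 for DE minus DC (0.81, adjusted p = 0.101), which left 1 subcluster. The stem and multipotent-like share for DC minus WT (-0.60, adjusted p = 0.0313) and Zeb2 in basophil and mast-like cells for DE minus DC (0.56, adjusted p = 0.00231) passed under the block.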

Other observations

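Of the tests in this part, only the restriction to the cluster shared by the genotypes was chosen after the data were seen. In basophil and mast-like cells of DC, Muc20, a mucin gene, rose from 0.849 ± 0.154 to 17.4 ± 2.10 CPM (log2 fold change 4.28 ± 0.45, adjusted p = 1.27e-07) by edgeR's quasi-likelihood test with 3 mice per genotype, as in the rest of this part. In megakaryocyte-like cells Wdfy1 was higher in DE than in DC, going from 21.5 ± 4.02 to 55.7 ± 5.01 CPM (log2 fold change 1.33 ± 0.17, adjusted p = 5.62e-05). The genes that changed in basophil and mast-like cells numbered 666 for DC minus WT (428 without WT mouse 3 and 398 without DC mouse 1). They numbered 682 for DE minus WT (442 without WT mouse 1 and 441 without DE mouse 1). They numbered 53 for DE minus DC (27 without DC mouse 1, 23 without DE mouse 1 and 86 without DE mouse 3). Those in erythroid-like cells, where the summed Neutrophil list was also higher in the variants, numbered 334 for DC minus WT (218 without WT mouse 1, 208 without WT mouse 2, 219 without DC mouse 1 and 192 without DC mouse 3). They numbered 823 for DE minus WT (416 without WT mouse 1, 372 without WT mouse 2, 1362 without WT mouse 3, 379 without DE mouse 1 and 390 without DE mouse 2). They numbered 316 for DE minus DC (550 without WT mouse 3, 156 without DC mouse 1, 159 without DC mouse 2, 167 without DC mouse 3, 75 without DE mouse 1 and 76 without DE mouse 2). Those in megakaryocyte-like cells numbered 45 for DC minus WT (26 without WT mouse 1, 25 without WT mouse 3, 19 without DC mouse 2 and 69 without DE mouse 3). They numbered 129 for DE minus WT (65 without WT mouse 1, 80 without DE mouse 1, 67 without DE mouse 2 and 240 without DE mouse 3). They numbered 35 for DE minus DC (15 without DC mouse 2, 20 without DC mouse 3, 16 without DE mouse 1 and 23 without DE mouse 2).

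In lymphoid progenitor-like cells Sdc1, which encodes syndecan-1, fell from 33.9 ± 12.8 to 5.17 ± 3.90 CPM (log2 fold change -2.55 ± 0.46, adjusted p = 0.0024) in DC (-1.50 with classes from the WT library alone, -1.69 at Leiden resolution 1 and -3.43 without DC mouse 2). The genes that changed numbered 245 for DC minus WT (128 without WT mouse 1, 112 without WT mouse 3, 110 without DC mouse 1, 155 without DC mouse 2 and 142 without DC mouse 3). They numbered 416 for DE minus WT (269 without WT mouse 1, 261 without WT mouse 3, 262 without DE mouse 2 and 271 without DE mouse 3). They numbered 24 for DE minus DC (9 without DC mouse 2, 10 without DC mouse 3 and 9 without DE mouse 1).

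In T, NK and innate lymphoid-like cells the immediate early genes Fosb and Jun were higher in DC than in WT. Fosb rose from 252 ± 49.2 to 714 ± 94.2 CPM (log2 fold change 1.45 ± 0.19, adjusted p = 0.000968) and Jun from 344 ± 36.7 to 724 ± 43.1 CPM (log2 fold change 1.03 ± 0.17, adjusted p = 0.00675). The predicted gene Gm10076 fell from 944 ± 114 to 499.8 ± 49.6 CPM (log2 fold change -0.96 ± 0.14, adjusted p = 0.000968). The call was lost for Fosb at Leiden resolution 1, in thinned cells and in the cluster shared by the genotypes (1.40, 1.04 and 1.24). It was lost for Jun with only cells with several hashtags removed (0.70) and without WT mouse 1 or WT mouse 3 (1.02 and 0.98). In DE, Stxbp6 rose from 24.3 ± 9.97 to 213 ± 68.3 CPM (log2 fold change 2.99 ± 0.32, adjusted p = 1.94e-05). It was 2.38 with classes from the WT library alone, 2.17 at Leiden resolution 1 and 3.60 in thinned cells. Against DC, Igf1r, the insulin-like growth factor 1 receptor, was higher in DE, from 109 ± 33.0 to 324 ± 54.1 CPM (log2 fold change 1.499 ± 0.20, adjusted p = 0.000216). Lgals1, the galectin-1 gene, was lower, from 369 ± 62.2 to 144 ± 17.8 CPM (log2 fold change -1.40 ± 0.18, adjusted p = 0.000216). Zeb2 was at 182 ± 38.2 CPM in WT, 160.5 ± 31.8 in DC and 83.6 ± 1.52 in DE. DE fell against WT (-1.22 ± 0.19, adjusted p = 0.000714) and DC (-0.96 ± 0.19, adjusted p = 0.0152). The latter call was lost without DC mouse 2 (-0.98), DC mouse 3 (-0.81), DE mouse 1 (-0.97) and DE mouse 2 (-0.95). The makeup of the class differed, with cluster 32 holding 85.6%, 79.3% and 54.7% of it in WT, DC and DE and cluster 35 14.4%, 20.7% and 45.3%. In cluster 32 alone, the shared one, DE against WT was -0.83 (adjusted p = 0.0263) and the call against DC was lost (-0.68, adjusted p = 0.128). There Igf1r was at 1.69 and Lgals1 at -1.03, both past the test, Stxbp6 gave no value, and 7, 52 and 17 genes changed (DC minus WT, DE minus WT and DE minus DC). The genes that changed numbered 3 for DC minus WT (5 without WT mouse 2, 12 without DC mouse 1, 11 without DE mouse 2 and 9 without DE mouse 3). They numbered 149 for DE minus WT (44 without WT mouse 2, 52 without WT mouse 3, 57 without DE mouse 1, 52 without DE mouse 2 and 368 without DE mouse 3). They numbered 28 for DE minus DC (48 without WT mouse 1, 147 without DC mouse 1, 6 without DC mouse 2, 16 without DC mouse 3, 6 without DE mouse 1, 9 without DE mouse 2 and 295 without DE mouse 3).

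Igkc, an immunoglobulin light chain gene of a multigene family and uncertain for that reason, was lower in DE than in WT in classes that do not make antibodies. It went from 43.3 ± 2.09 to 2.71 ± 1.16 CPM (log2 fold change -3.93 ± 0.25) in megakaryocyte-like cells, from 52.0 ± 0.910 to 7.02 ± 1.06 CPM (log2 fold change -2.88 ± 0.20) in basophil and mast-like cells and from 35.4 ± 0.624 to 4.15 ± 0.446 CPM (log2 fold change -3.09 ± 0.11) in erythroid-like cells. It was -3.28, -3.35 and -3.15 in megakaryocyte-like cells with classes from the WT library alone, at Leiden resolution 1 and in thinned cells. In erythroid-like cells the call was lost with the hashtag ratio rule (-5.00). Plasma cell-like cells made up 0.858% of WT, 0.485% of DC and 0% of DE cells, where 0 of 12333 cells allow up to 0.0243%.

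The 6 mice of a contrast split into 3 and 3 in 10 ways, which are too few for a share under 0.05, so only the real value and the highest of the other splits are given (DC minus WT, DE minus WT and DE minus DC). For genes changed they are given by class. The stem and multipotent-like class gave 877 against 0, 1342 against 1 and 34 against 0. The neutrophil-like class gave 7051 against 0, 7996 against 0 and 1365 against 0. The monocyte-like class gave 5609 against 0, 4138 against 0 and 1550 against 0. The cDC-like class gave 371 against 4, 443 against 0 and 217 against 2. The lymphoid progenitor-like class gave 245 against 0, 416 against 0 and 24 against 2. The T, NK and innate lymphoid-like class gave 3 against 6, 149 against 23 and 28 against 3. The megakaryocyte-like class gave 45 against 0, 129 against 2 and 35 against 31. The erythroid-like class gave 334 against 43, 823 against 0 and 316 against 0. The basophil and mast-like class gave 666 against 1, 682 against 1 and 53 against 2. For gene lists they were 6 against 10, 8 against 6 and 8 against 5 in the stem and multipotent-like class. They were 2 against 4, 2 against 3 and 7 against 7 in the neutrophil-like class. They were 6 against 7, 9 against 9 and 5 against 8 in the monocyte-like class. They were 7 against 9, 8 against 7 and 7 against 5 in the cDC-like class. For class shares they were 8 against 0, 12 against 0 and 4 against 0. For dendritic subclusters they were 7 against 0, 8 against 0 and 2 against 0. Counting the real one, the number of splits with a result as large was 1 in every case except the next ones. It was 2 for gene lists of neutrophil-like DE minus DC, monocyte-like DE minus WT, cDC-like DC minus WT. It was 4 for gene lists of stem and multipotent-like DC minus WT, neutrophil-like DE minus WT, monocyte-like DE minus DC. It was 5 for gene lists of monocyte-like DC minus WT. It was 7 for gene lists of neutrophil-like DC minus WT. It was 2 for genes changed in T, NK and innate lymphoid-like cells, DC minus WT.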
